A study of Schizosaccharomyces pombe with 21 samples.

How the data were processed

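PolyA RNA was measured by RNA sequencing in 21 libraries of the fission yeast Schizosaccharomyces pombe, 7 groups with 3 replicates each. Per the labels, wild-type cells and cells of a quadruple mutant called HASX grew to log phase in a phosphate-replete medium and were moved to the same medium without phosphate for 1, 2 or 4 h. The wild type was also sampled at 0 h, in the phosphate-replete medium. Libraries were made with a stranded TruSeq mRNA kit and sequenced paired-end, per the labels.

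Per the submitters' processing notes, HISAT2 2.1.0, SAMtools, HTSeq 0.10.0 and DESeq2 were used with genome build ASM294v2. The notes give no role, order or settings for these tools, so the strand setting of the counting is unknown. Counts of antisense and overlapping non-coding RNAs can therefore not be separated from those of the genes they overlap, and how reads of near-identical paralogs were divided is not known either. The deposited count tables hold 1 integer count per gene and library for 6988 gene identifiers, with the wild type and HASX in separate tables. Beside these, the authors deposited 6 tables of DESeq2 results against the wild type at 0 h, 1 per starved group, whose fold changes are log2 values per the file headers. The same deposited tables give an adjusted p-value for each gene, per the file headers. All values reported below were computed from the deposited counts, and the deposited fold changes were used only to check the counts.

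Gene identifiers were matched to the annotation of a later build, ASM294v3, for names, gene types and the order of genes only. Of the 6988 identifiers, 6836 matched a locus tag, 12 a synonym and 140 neither. By gene type, 5109 were protein-coding, 1855 non-coding and 24 unclassified, where an identifier with the prefix of a non-coding RNA counted as non-coding. Shares of counts by class follow the annotation instead, with 5111 protein-coding, 36 mitochondrial and 104 unclassified identifiers. Positions in the annotation served only to order the genes, and none are given here. The gene called spx1 in the labels is pqr1 in the annotation and is named pqr1 here.

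Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 6234 genes and took out 754. Library sizes were scaled with TMM. A quasi-likelihood model with 1 mean per group was fitted to all 21 libraries, with 14 residual degrees of freedom and a common biological coefficient of variation of 0.212. A gene was counted as higher or lower when its Benjamini-Hochberg adjusted p was under 0.05 and its fold change was at least 2-fold. Members of gene lists and named genes were counted at the adjusted p alone. Levels are counts-per-million (CPM) on TMM-scaled library sizes, given as mean ± SD over 3 replicates. Fold changes are log2 values. Where a group had no counts, a floor of 3 counts per library was used for a lower bound, and such floors cover counting error only.

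Comparisons were the wild type at each time against 0 h, HASX against the wild type at the same time, 4 h against 1 h in each genotype, and the difference between those 2 changes as an interaction. HASX was also compared with the wild type at 0 h. A HASX sample at 0 h and a mock transfer to fresh replete medium were not among the groups analysed, and the labels give no batch.

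Before the data were examined, the groups, the comparisons, the thresholds, the alternatives, 30 gene lists and the rule for named genes were fixed. The rule names the 4 engineered genes and the 3 genes of the phosphate acquisition regulon. For each main comparison it adds the 8 higher and 8 lower protein-coding genes with the largest change among those with adjusted p under 0.05, a mean of at least 10 CPM and replicates that did not overlap between the groups. It also takes up to 4 genes per list with the largest change among those past the test. Genes chosen after their values were seen are pointed out as such. Among the genes picked by the size of their change, 1 is not reported here. The lists cover the phosphate acquisition regulon, other phosphate and polyphosphate genes, inositol phosphate kinases and phospholipase C, phospholipid and inositol metabolism, cytosolic ribosomal proteins, ribosome biogenesis factors, RNA polymerase I and III, translation factors, the core environmental stress response, chaperones and heat shock genes, the unfolded protein response, iron acquisition, copper and zinc transport, glucose-repressed and hexose transport genes, glycolysis and fermentation, the TCA cycle and respiratory chain, nitrogen starvation genes, mating and early meiosis, P-cell specific genes, autophagy, G1/S genes, histones, mitosis and septation, thiamine-regulated genes, amino acid biosynthesis, purine and pyrimidine synthesis, sterol synthesis and hypoxia, flocculins and cell surface genes, the proteasome, and RNA 3' processing and termination.

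Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over 270 tests (30 lists in 9 comparisons). Of these tests, 109 passed an adjusted p of 0.05. With the correlation estimated from the data, 0 passed, and beside lists described as passing the adjusted p with an estimated correlation, or its range, is given. The tests of fry, which ask whether a list's genes move on balance in 1 direction without comparing them with other genes, passed for 163.

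Alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors (RLE) in place of TMM, no filter, a filter of at least 10 CPM in at least 3 libraries, only the groups compared in the model, the replicate number as a block, counts thinned to 11235668 per library, and leaving out each replicate in turn. Leaving out HASX 4 h replicate 3 from comparisons that do not use it was added after the data were seen. The median of all genes moved by at most 0.09 between RLE and TMM. The numbering of replicates did not pair libraries across all groups: of 63 pairs with the same number, 18 had a correlation of residuals over 0.1. These correlations ran from -0.81 to 0.7, and 11 of 21 libraries correlated best with a library of their own number. Pairing within some groups is therefore not excluded.

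The model was tested on simulated data drawn from the levels and spreads of these genes, with 100 genes changed 2-fold and 100 changed 4-fold in each of 2 comparisons. At 2-fold it recovered 76% of the changed genes in the wild type at 1 h against 0 h and 73% in HASX against the wild type at 4 h. At 4-fold these were 93% and 92%. Of unchanged genes, 0.12% and 0.08% were called. A simulated list of 50 doubled genes was found by camera, and 0 of 50 unchanged lists had p under 0.05. Genes were drawn independently of each other, so the simulation does not test the preset correlation between genes. It also changed far fewer genes than the 43.3% called in HASX against the wild type at 4 h, and held no library set apart from its group. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.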

Results

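PolyA RNA was sequenced from wild-type fission yeast and from HASX, a strain that lacks the catabolic enzymes of inositol pyrophosphates, signalling molecules tied to phosphate status. HASX carries a point mutation in asp1 that removes the pyrophosphatase activity of this kinase and pyrophosphatase, and deletions of aps1 (a Nudix hydrolase), siw14 (a cysteine phosphatase) and pqr1 (spx1 in the labels, an SPX-domain ubiquitin ligase). There were 7 groups of 3 replicates: the wild type in replete medium (0 h) and after 1, 2 and 4 h without phosphate, and HASX after 1, 2 and 4 h without phosphate. Libraries held between 11.24 M and 23.68 M counts. Group means were 19.3 M ± 2.47 M counts (SD, n = 3) for the wild type at 0 h, 18.8 M ± 1.51 M at 1 h, 22.0 M ± 2.70 M at 2 h and 19.5 M ± 1.33 M at 4 h. For HASX they were 16.6 M ± 2.22 M at 1 h, 16.0 M ± 2.09 M at 2 h and 15.5 M ± 3.76 M at 4 h. The first principal component of log2 CPM held 77.3% of the variance and the second 7.0%. Replicates of a group correlated across genes at 0.987 to 0.999, apart from HASX 4 h replicate 3, which correlated at 0.929 and 0.928 with the other two.

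The engineered loci set HASX apart from the wild type. Transcripts of the 3 deleted genes were low in HASX at every time: aps1 (SPAC13G6.14) was at 179 ± 9.09 CPM (n = 3) in the wild type and 4.45 ± 0.693 in HASX at 1 h, and siw14 (SPBC17A3.03c) at 144 ± 5.28 and 3.21 ± 0.446. The pqr1 gene (SPAC6B12.07c) kept more of its counts, with 320 ± 3.89 CPM in the wild type and 49.9 ± 1.76 in HASX at 1 h. All 9 tests of these genes found them lower in HASX. For aps1 the log2 fold changes were -5.32, -5.80 and -4.37 at 1, 2 and 4 h (adjusted p = 3.65e-12, 1.62e-12 and 5.67e-11), and for pqr1 -2.68, -2.70 and -1.92. For siw14 they were -5.48, -6.93 and -3.28, where the value at 4 h rested on HASX 4 h replicate 3 and was -6.74 without it. With only the groups compared in the model its call at 4 h was lost (-3.3, adjusted p = 0.069). The mutated asp1 (SPCC1672.06c) is still transcribed, and its log2 fold changes were 0.70 at 1 h (adjusted p = 0.0532), 0.72 at 2 h (adjusted p = 0.0459) and 0.87 at 4 h (adjusted p = 0.0183). The call at 2 h was lost when any 1 of the 6 libraries was left out, for example at 0.61 (adjusted p = 0.14) without WT 2 h replicate 1. At 4 h the change was -0.02 without HASX 4 h replicate 3 (adjusted p = 0.898), and its call was also lost without WT 4 h replicate 2 (0.78, adjusted p = 0.0667). The marker ura4, which replaces spx1 in HASX per the labels, had 0 counts in the 12 wild-type libraries and 745 ± 84.4, 863 ± 61.7 and 677 ± 47.9 CPM in HASX at 1, 2 and 4 h. That is at least 5030-, 6290- and 4850-fold higher against a floor of 3 counts per library.

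The wild type after 1 h without phosphate was compared with 0 h for the early response to starvation. The 3 genes of the phosphate acquisition regulon rose: the acid phosphatase gene pho1 (SPBP4G3.02) from 1220 ± 148 to 4944 ± 398 CPM (n = 3), the phosphate transporter gene pho84 (SPBC8E4.01c) from 1344 ± 206 to 2924 ± 166, and the glycerophosphodiester transporter gene tgp1 (SPBC1271.09) from 53.8 ± 8.78 to 257 ± 22.2. A further phosphate transporter gene, pho842, rose from 329 ± 22.5 to 1030 ± 35.0 CPM. Among the largest falls were those of the uracil-regulated genes urg1 and urg2 and the pyrimidine salvage gene uck2: urg1 went from 7251 ± 1383 to 417 ± 100 CPM, urg2 from 6570 ± 1403 to 422 ± 87.6 and uck2 from 728 ± 103 to 52.2 ± 10.03. The oligopeptide transporter gene isp4 fell from 657 ± 10.6 to 80.8 ± 20.2 CPM and the ferric reductase gene frp1 from 584 ± 70.6 to 54.5 ± 28.6.

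In that comparison 48 genes were higher and 89 lower, 2.2% of those tested. The log2 fold changes were 2.02 for pho1 (adjusted p = 4.47e-09), 1.12 for pho84 (adjusted p = 5.49e-06), 2.26 for tgp1 (adjusted p = 1.59e-09), 1.65 for pho842 (adjusted p = 2.22e-08), -4.12 for urg1 (adjusted p = 1.02e-11), -3.96 for urg2 (adjusted p = 1.14e-11), -3.80 for uck2 (adjusted p = 4.7e-12), -3.02 for isp4 (adjusted p = 5.41e-11) and -3.42 for frp1 (adjusted p = 6.73e-05). All 3 regulon genes were higher, also when adjusted over the list alone. For the regulon camera gave adjusted p = 4.31e-09, and adjusted p = 0.0684 with an estimated correlation. Of 12 iron acquisition genes, 1 rose, 9 fell and 2 did not pass (1 up and 10 down adjusted over the list alone), with a median of -2.07. Camera put the iron list at adjusted p = 4.32e-09, and at adjusted p = 0.254 with an estimated correlation. Among them fip1 fell by 2.76. The siderophore transporter gene str3 stood at -3.77 (adjusted p = 0.0148), a call lost without WT 1 h replicate 1 (-3.45, adjusted p = 0.089) or replicate 2 (-3.31, adjusted p = 0.0775).

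Of 24 nitrogen starvation genes in the wild type at 1 h, 2 were higher, 11 lower and 11 not called (3 up and 11 down adjusted over the list alone), among them the amino acid permease genes isp5 at -2.48 and per1 at -2.43. With camera the nitrogen list had adjusted p = 1.15e-07, and adjusted p = 0.47 with an estimated correlation. Of 10 histone genes 9 rose and 1 did not pass (9 adjusted over the list alone), with a median of 0.51 and hhf2 at 0.76. For histones camera gave adjusted p = 2.61e-07, and adjusted p = 0.481 with an estimated correlation. Flocculins and cell surface genes had 1 of 26 higher, 5 lower and 20 not called (1 up and 7 down adjusted over the list alone; camera adjusted p = 0.0017; adjusted p = 0.644 with an estimated correlation), a call lost without WT 0 h replicate 3 (adjusted p = 0.0769). Ribosomal protein genes stood at a median of -0.02, with 1 of 141 higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.711). Without a mock transfer, the change of medium and the loss of phosphate are not separated in this comparison.

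After 2 h without phosphate the regulon was again above its level at 0 h, with 8759 ± 1345 CPM (n = 3) for pho1, 4883 ± 629 for pho84 and 454 ± 61.0 for tgp1. Among the largest rises outside it were SPBC1289.14, an adducin-family gene (3.41), ecl3 (2.96) and the F-box gene pof15, which went from 13.0 ± 2.71 to 83.8 ± 12.6 CPM (2.69). The amino acid permease gene nrg1 fell from 274 ± 62.7 to 57.6 ± 5.0 CPM (-2.25), and isp4 stood at -2.40 and frp1 at -3.33. Genes of the TCA cycle and respiratory chain leaned upward, with 13 of 47 higher, 0 lower and 34 not called (24 up and 0 down adjusted over the list alone), at a median of 0.31. Camera put the respiratory list at adjusted p = 2.57e-05, and at adjusted p = 0.76 with an estimated correlation. Medians of ribosome biogenesis factors (-0.28) and of RNA polymerase I and III genes (-0.19) were negative at 2 h, with ribosomal proteins at 0.01.

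Against 0 h, 78 genes were higher and 63 lower at 2 h (2.3% of those tested), with 51 higher when only the groups compared were in the model. The log2 fold changes were 2.84 for pho1 (adjusted p = 1.29e-10), 1.86 for pho84 (adjusted p = 1.38e-08) and 3.08 for tgp1 (adjusted p = 1.14e-10), with camera at adjusted p = 1.38e-08 for the 3 genes and adjusted p = 0.0684 with an estimated correlation. Of 11 other phosphate and polyphosphate genes, 5 were higher, 1 lower and 5 not called (7 up and 3 down adjusted over the list alone), at a median of 0.30. With camera the other phosphate genes had adjusted p = 0.00934, and adjusted p = 0.573 with an estimated correlation. Of 10 thiamine-regulated genes 5 were higher and 5 not called (6 up adjusted over the list alone). For the thiamine list camera gave adjusted p = 0.00231, and adjusted p = 0.575 with an estimated correlation. Iron acquisition genes had 1 of 12 higher, 7 lower and 4 not called (1 up and 7 down adjusted over the list alone; camera adjusted p = 2.57e-05; adjusted p = 0.47 with an estimated correlation). Among them str3 was at -3.94, at -6.48 without WT 2 h replicate 3, and at -3.48 without WT 2 h replicate 1 (adjusted p = 0.0581). The count of lower genes was set by single libraries: it was 40 without WT 2 h replicate 1, 221 without WT 2 h replicate 3, 101 without WT 0 h replicate 3 and 118 without HASX 4 h replicate 3.

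At 4 h more genes passed the test in the wild type than at 1 h or 2 h. The regulon reached 18460 ± 724 CPM (n = 3) for pho1, 6631 ± 104 for pho84 and 1004 ± 23.8 for tgp1. The L-lactate dehydrogenase gene SPAPB1A11.03 went from 0.928 ± 0.553 to 134 ± 13.4 CPM, the metallothionein gene zym1 from 14.7 ± 2.43 to 251 ± 2.27 and ecl3, one of a family of genes that extend chronological lifespan, from 7.24 ± 0.999 to 126 ± 12.1. Genes for making ribosomes fell together: rpl1603 went from 106 ± 13.2 to 10.7 ± 0.737 CPM, rpl1002 from 767 ± 125 to 168 ± 7.01, and the nucleolar gene nhp2 from 266 ± 41.8 to 70.2 ± 3.86. Ribosomal protein paralogs are nearly identical in sequence, so the division of reads between them is uncertain.

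At 4 h 509 genes were higher and 566 lower than at 0 h, 17.2% of those tested. The log2 fold changes were 3.92 for pho1 (adjusted p = 2.89e-13), 2.30 for pho84 (adjusted p = 1.04e-10), 4.22 for tgp1 (adjusted p = 2.3e-13), 7.19 for SPAPB1A11.03 (adjusted p = 4.39e-13) and 4.10 for zym1 (adjusted p = 1.31e-13). Of 141 ribosomal protein genes 139 fell and 2 did not pass (139 adjusted over the list alone), at a median of -1.48. Camera put ribosomal proteins at adjusted p = 1.01e-59, and at adjusted p = 0.254 with an estimated correlation. Ribosome biogenesis factors had 83 of 92 lower, 0 higher and 9 not called (84 down adjusted over the list alone), at a median of -1.03. With camera ribosome biogenesis had adjusted p = 1.08e-21, and adjusted p = 0.0684 with an estimated correlation. Of 25 genes for RNA polymerase I and III, 22 fell and 3 did not pass (23 adjusted over the list alone), at a median of -0.72. For the polymerase list camera gave adjusted p = 1.75e-07, and adjusted p = 0.0684 with an estimated correlation. Of 36 translation factor genes 32 fell and 4 did not pass (32 adjusted over the list alone), at a median of -0.55. Camera put translation factors at adjusted p = 8.19e-10, and at adjusted p = 0.392 with an estimated correlation.

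Upward lists at 4 h in the wild type included those of stress, respiration, mating and autophagy. In the core environmental stress response 29 of 38 genes were higher, 4 lower and 5 not called (29 up and 4 down adjusted over the list alone), at a median of 0.97, with the fructose bisphosphatase gene fbp1 at 3.88 and tms1 at 2.61. With camera the stress response list had adjusted p = 4.31e-09, and adjusted p = 0.575 with an estimated correlation. Of 47 genes of the TCA cycle and respiratory chain 39 were higher, 0 lower and 8 not called (40 up and 1 down adjusted over the list alone), at a median of 0.52 with mdh1 at 1.30. For the respiratory list camera gave adjusted p = 2.69e-07, and adjusted p = 0.662 with an estimated correlation. In mating and early meiosis 20 of 27 were higher, 0 lower and 7 not called (20 up adjusted over the list alone), at a median of 1.01, with the meiotic cohesin gene rec8 at 2.31 and the pheromone gene mfm1 at 2.11. Camera put the mating list at adjusted p = 2.88e-06, and at adjusted p = 0.0684 with an estimated correlation. In autophagy 17 of 23 were higher, 1 lower and 5 not called (18 up and 1 down adjusted over the list alone), at a median of 0.71 with atg43 at 2.21. With camera the autophagy list had adjusted p = 5.84e-06, and adjusted p = 0.323 with an estimated correlation. Of 17 glycolysis and fermentation genes 13 were higher and 4 not called (13 adjusted over the list alone). For the glycolysis list camera gave adjusted p = 0.00012, and adjusted p = 0.601 with an estimated correlation. All 10 histone genes were higher (10 adjusted over the list alone; camera adjusted p = 0.00267; adjusted p = 0.684 with an estimated correlation). Of 21 glucose-repressed genes 11 were higher, 3 lower and 7 not called (12 up and 3 down adjusted over the list alone; camera adjusted p = 0.00469; adjusted p = 0.601 with an estimated correlation). The regulon passed at camera adjusted p = 6.62e-05 (adjusted p = 0.304 with an estimated correlation) and the list of other phosphate genes at camera adjusted p = 0.0281 (adjusted p = 0.594 with an estimated correlation).

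Of 60 amino acid biosynthesis genes at 4 h in the wild type 21 were lower, 3 higher and 36 not called (3 up and 21 down adjusted over the list alone), at a median of -0.07. With camera that list had adjusted p = 0.0424, and adjusted p = 0.954 with an estimated correlation. Its call was lost with DESeq2 size factors (adjusted p = 0.0598), without WT 0 h replicate 3 (adjusted p = 0.259) and without WT 4 h replicate 3 (adjusted p = 0.0644). Lists that did not pass also held changed members. Among inositol phosphate kinases and phospholipase C, 1 of 5 genes was higher and 1 lower (1 and 1 adjusted over the list alone), with a median of -0.05 and a test in the upward direction (camera adjusted p = 0.985). Of 21 phospholipid and inositol genes 8 were higher, 5 lower and 8 not called (9 up and 5 down adjusted over the list alone; camera adjusted p = 0.392). Copper and zinc transport had 6 of 12 higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.444). Of 29 G1/S genes 6 were higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.817), and of 34 proteasome genes 7 were higher and 6 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.945). For RNA 3' processing and termination 4 of 26 were higher and 9 lower (4 and 9 adjusted over the list alone), at a median of -0.29 (camera adjusted p = 0.382). Of 5 P-cell genes 3 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.265).

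Between 1 h and 4 h in the wild type, urg1, urg2 and uck2 rose again and ribosome genes declined. Levels of urg1 rose from 417 ± 100 to 5330 ± 166 CPM (n = 3), a log2 change of 3.68, with urg2 at 3.38 and uck2 at 3.29. The gene stb3, a homolog of a budding yeast regulator of ribosome biogenesis genes, rose from 50.1 ± 4.07 to 626 ± 14.1 CPM (3.64, adjusted p = 2.15e-13), while the adenine phosphoribosyltransferase gene apt1 fell from 414 ± 16.8 to 83.3 ± 3.48 CPM (-2.31). In that comparison 434 genes were higher and 435 lower. Of 141 ribosomal protein genes 140 fell and 1 did not pass (140 adjusted over the list alone), at a median of -1.48. Camera put ribosomal proteins at adjusted p = 1.76e-67, and at adjusted p = 0.204 with an estimated correlation. Of 21 glucose-repressed and hexose transport genes 15 rose and 6 did not pass (15 adjusted over the list alone), at a median of 0.67. With camera the glucose-repressed list had adjusted p = 1.5e-05, and adjusted p = 0.418 with an estimated correlation. Of 24 nitrogen starvation genes 15 were higher, 3 lower and 6 not called (16 up and 3 down adjusted over the list alone). For the nitrogen list camera gave adjusted p = 0.000873, and adjusted p = 0.662 with an estimated correlation.

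**Figure D1:**
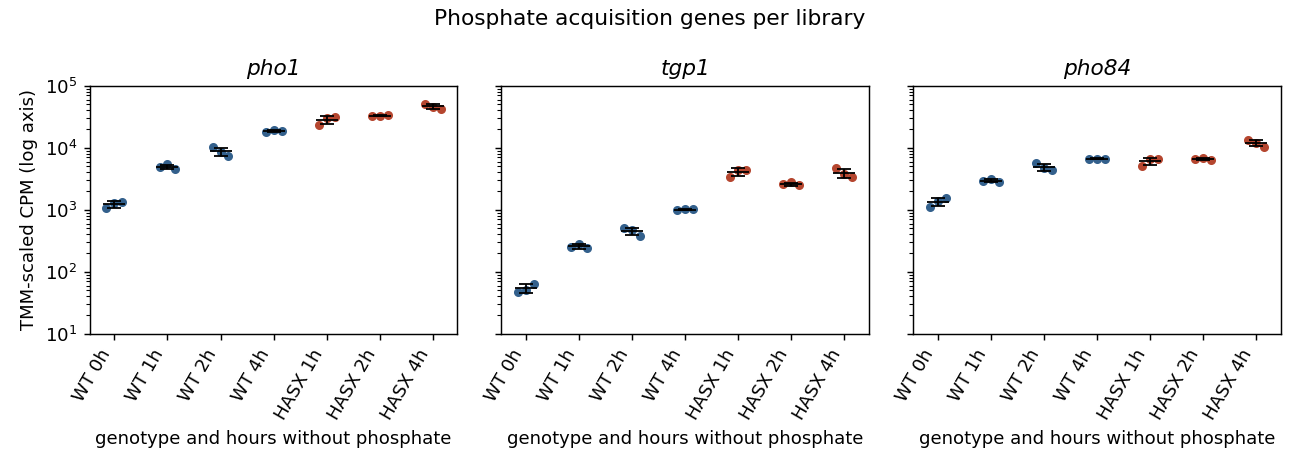
Levels of pho1, tgp1 and pho84 in TMM-scaled CPM (vertical axis, log scale) by genotype and hours without phosphate (horizontal axis), with 1 point per library and black bars for the mean ± SD of 3 replicates. At 1 h pho1 stood at 4944 CPM in the wild type and 28112 in HASX, and tgp1 at 257 and 4068.

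HASX and the wild type were next compared at 1 h without phosphate. Beside the lost catabolic enzymes of inositol pyrophosphates, HASX lacks the ubiquitin ligase gene pqr1 and carries ura4. Effects of these changes are not separated in the comparisons between the strains. The phosphate genes pho1 and tgp1 stood far higher in HASX, pho1 at 28112 ± 4113 against 4944 ± 398 CPM (n = 3) and tgp1 at 4068 ± 570 against 257 ± 22.2, while pho84 stood at 6092 ± 806 against 2924 ± 166. The stress gene ddr48 was at 4506 ± 243 CPM against 22.8 ± 3.21, the invertase gene inv1 at 929 ± 85.3 against 8.94 ± 0.452, and atf21, a bZIP transcription factor gene, at 102 ± 24.1 against 0.588 ± 0.0418. Lower in HASX were the ribosomal protein gene rps1402 (35.0 ± 5.19 against 1112 ± 21 CPM), apt1 (10.8 ± 2.81 against 414 ± 16.8) and mfm2, which encodes the M-factor mating pheromone (4.51 ± 2.71 against 201 ± 17.9).

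At 1 h 1472 genes were higher and 1371 lower in HASX, 45.6% of those tested. The log2 fold changes were 2.51 for pho1 (adjusted p = 4.19e-12), 1.06 for pho84 (adjusted p = 3.75e-07), 3.98 for tgp1 (adjusted p = 1.36e-14), 7.63 for ddr48 (adjusted p = 2.53e-16), 6.70 for inv1 (adjusted p = 2.32e-16) and -5.48 for mfm2 (adjusted p = 2.03e-12). The regulon passed with camera at adjusted p = 0.0256 (3 of 3 higher, also adjusted over the list alone), and had adjusted p = 0.594 with an estimated correlation. All 141 ribosomal protein genes were lower, also when adjusted over the list alone, at a median of -2.98. Camera put ribosomal proteins at adjusted p = 4.71e-40, and at adjusted p = 0.41 with an estimated correlation. Of 92 ribosome biogenesis factors 79 were lower, 7 higher and 6 not called (8 up and 79 down adjusted over the list alone), at a median of -1.38. With camera ribosome biogenesis had adjusted p = 8.19e-10, and adjusted p = 0.358 with an estimated correlation. Translation factors had 33 of 36 lower, 1 higher and 2 not called (1 up and 33 down adjusted over the list alone), at a median of -1.08 with tif11 at -3.08. For translation factors camera gave adjusted p = 8.58e-08, and adjusted p = 0.47 with an estimated correlation.

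The core stress response, autophagy and glucose-repressed lists were higher in HASX at 1 h, and the unfolded protein response was lower. The core environmental stress response had 30 of 38 genes higher, 7 lower and 1 not called (30 up and 7 down adjusted over the list alone), at a median of 1.48 with the glycerol dehydrogenase gene gld1 at 6.18. Camera put the stress response list at adjusted p = 1.29e-05, and at adjusted p = 0.662 with an estimated correlation. Of 23 autophagy genes 16 were higher, 3 lower and 4 not called (16 up and 3 down adjusted over the list alone), at a median of 1.04 with atg1 at 3.65. With camera the autophagy list had adjusted p = 0.000448, and adjusted p = 0.47 with an estimated correlation. Of 21 glucose-repressed genes 16 were higher, 4 lower and 1 not called (16 up and 4 down adjusted over the list alone), at a median of 1.64. For the glucose-repressed list camera gave adjusted p = 0.00234, and adjusted p = 0.579 with an estimated correlation. Genes of the unfolded protein response were lower in 13 of 16 cases and higher in 2 (13 and 2 adjusted over the list alone), at a median of -0.98, with the ER chaperone gene bip1 at -1.93. Camera put the unfolded protein response list at adjusted p = 0.00792, and at adjusted p = 0.601 with an estimated correlation. The median of this list was also negative at 2 h (-1.05) and 4 h (-0.6). Chaperones and heat shock genes had 10 of 26 higher, 13 lower and 3 not called at 1 h (10 up and 14 down adjusted over the list alone), at a median of -0.62 (camera adjusted p = 0.449). Of all long non-coding RNAs tested, 525 of 1118 (47.0%) were higher and 130 lower, against 896 of 5005 protein-coding genes higher (17.9%). The shares of counts of snoRNA, snRNA and rRNA were higher in HASX at 1 h as well, by 3.85, 13.9 and 6.54 times (3.51, 6.18 and 2.99 times without HASX 1 h replicate 2), without overlap of libraries, which chance gives in 10% of comparisons of 3 with 3. HASX and wild-type libraries come in separate count tables and the labels give no batch, so genotype and batch cannot be told apart.

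At 2 h HASX was compared with the wild type again. The small heat shock protein gene hsp16 was at 15410 ± 1155 CPM (n = 3) in HASX and 119 ± 7.73 in the wild type, the Hsp70 gene ssa1 at 4342 ± 226 and 116 ± 8.53, and atf21 at 317 ± 27.2 and 0.979 ± 0.294. Lower in HASX were mfm2 (3.10 ± 0.808 against 279 ± 18.0 CPM), rpl1002 (20.7 ± 3.48 against 726 ± 112), the endoglucanase gene eng1, which acts in cell separation (56.7 ± 2.68 against 954 ± 108), and met14, an adenylylsulfate kinase gene of sulfate assimilation (25.1 ± 2.67 against 412 ± 55.4). Levels of pho1 were 32946 ± 380 CPM in HASX and 8759 ± 1345 in the wild type, of tgp1 2605 ± 140 and 454 ± 61.0, and of pho84 6573 ± 191 and 4883 ± 629.

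At 2 h 1597 genes were higher and 1484 lower in HASX (49.4% of those tested). The log2 fold changes were 7.02 for hsp16, 5.22 for ssa1, -6.49 for mfm2, -5.13 for rpl1002, -4.07 for eng1 and -4.03 for met14. For pho1 the change was 1.91 (adjusted p = 1.76e-10), for pho84 0.43 (adjusted p = 0.00498) and for tgp1 2.52 (adjusted p = 4.46e-12), but the 3 genes did not pass the test against other genes (camera adjusted p = 0.0898). Of 60 amino acid biosynthesis genes 50 were lower, 3 higher and 7 not called (3 up and 50 down adjusted over the list alone), at a median of -1.05. With camera amino acid biosynthesis had adjusted p = 4.22e-08, and adjusted p = 0.662 with an estimated correlation. The median of this list in HASX against the wild type was also negative at 1 h (-0.51) and 4 h (-0.72). Mitosis and septation genes had 20 of 28 lower, 3 higher and 5 not called (3 up and 20 down adjusted over the list alone), at a median of -0.92 with the mitotic activator gene slp1 at -3.29. For mitosis and septation camera gave adjusted p = 0.00185, and adjusted p = 0.47 with an estimated correlation. Of 22 purine and pyrimidine synthesis genes 18 were lower, 1 higher and 3 not called (1 up and 18 down adjusted over the list alone), at a median of -1.07 with ura5 at -2.74. Camera put purine and pyrimidine synthesis at adjusted p = 0.00217, and at adjusted p = 0.684 with an estimated correlation. Of 28 sterol and hypoxia genes 20 were lower, 5 higher and 3 not called (5 up and 20 down adjusted over the list alone), at a median of -0.61 with erg6 at -2.91. With camera the sterol list had adjusted p = 0.0112, and adjusted p = 0.865 with an estimated correlation. All 141 ribosomal protein genes were lower, also adjusted over the list alone, at a median of -3.21. For ribosomal proteins camera gave adjusted p = 1.08e-37, and adjusted p = 0.418 with an estimated correlation. Chaperones and heat shock genes split, with 13 of 26 higher and 13 lower (13 and 13 adjusted over the list alone) and a median of -0.05 beside a mean of 0.54 (camera adjusted p = 0.985).

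At 4 h pho1 stood at 46824 ± 4544 CPM (n = 3) in HASX and 18460 ± 724 in the wild type, pho84 at 11942 ± 1402 and 6631 ± 104, and tgp1 at 3950 ± 647 and 1004 ± 23.8. The thiamine-repressed gene nmt1 was at 560 ± 41.5 CPM in HASX and 1.09 ± 0.244 in the wild type, and thi2, of thiamine synthesis, at 1261 ± 10 and 69.7 ± 2.05. The glyceraldehyde phosphate dehydrogenase gene gpd3 stood at 36216 ± 8456 CPM against 1930 ± 78.4, and pgk1, also of glycolysis, at 41120 ± 1966 against 5605 ± 179. Lower in HASX were mfm2 (3.22 ± 0.785 against 464 ± 61.1 CPM), the M-cell pheromone receptor gene mam2 (2.48 ± 0.762 against 43.0 ± 4.98) and eng1 (51.8 ± 1.15 against 807 ± 9.77).

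At 4 h 1541 genes were higher and 1161 lower in HASX (43.3% of those tested), and 1345 and 1183 without HASX 4 h replicate 3. The log2 fold changes were 1.34 for pho1 (adjusted p = 3.82e-08), 0.85 for pho84 (adjusted p = 7.39e-06), 1.98 for tgp1 (adjusted p = 2.31e-10), 9.0 for nmt1 (adjusted p = 6.76e-16), 4.18 for thi2, 4.23 for gpd3, 2.88 for pgk1, -7.16 for mfm2 (adjusted p = 3.61e-13), -4.09 for mam2 and -3.96 for eng1. All 3 regulon genes were higher, also adjusted over the list alone, with camera at adjusted p = 0.0565, and at adjusted p = 0.0419 without HASX 4 h replicate 3. Of 17 glycolysis and fermentation genes 15 were higher, 1 lower and 1 not called (15 up and 1 down adjusted over the list alone), at a median of 1.45. Camera put the glycolysis list at adjusted p = 1.8e-05, and at adjusted p = 0.575 with an estimated correlation. Ribosomal protein genes had 134 of 141 lower, 2 higher and 5 not called (2 up and 134 down adjusted over the list alone), at a median of -2.14. With camera ribosomal proteins had adjusted p = 1.1e-32, and adjusted p = 0.47 with an estimated correlation. Mitosis and septation genes had 20 of 28 lower, 1 higher and 7 not called (1 up and 20 down adjusted over the list alone), at a median of -1.06. For mitosis and septation camera gave adjusted p = 8.46e-05, and adjusted p = 0.347 with an estimated correlation. In mating and early meiosis 12 of 27 were higher and 12 lower (12 and 12 adjusted over the list alone; camera adjusted p = 0.834).

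Single genes at 4 h in HASX depended on replicate 3, which held 470 genes at least 4-fold above both other replicates, among 5749 with at least 50 counts in it. Among the largest changes, mug27 was at 8.95 and at 2.83 without that library, SPAC6C3.03c at 6.74 and 1.79, and tri1 at 6.53 and 0.64. From the list of RNA 3' processing and termination, iss1, cyp8 and pcf11 stood at 1.74, 1.62 and 1.45, and without that library at 0.18, 0.41 and -0.53. Long non-coding RNAs were higher in 646 of 1118 cases (57.8%) with all libraries and in 487 of 1123 (43.4%) without it, against 837 of 5005 (16.7%) and 799 of 5011 (15.9%) of protein-coding genes. In HASX at 4 h the shares of snoRNA, snRNA and rRNA were also 5.05, 19.1 and 22.8 times those of the wild type. Without HASX 4 h replicate 2 these were 3.54, 7.15 and 1.78 times. The authors' deposited fold changes for this group differed from DESeq2 on the deposited counts by a median of 0.191 (r = 0.970), where the other 5 groups differed by 0.00307 to 0.00995, so that table was not obtained from the deposited counts in the way the others were.

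**Figure D2:**
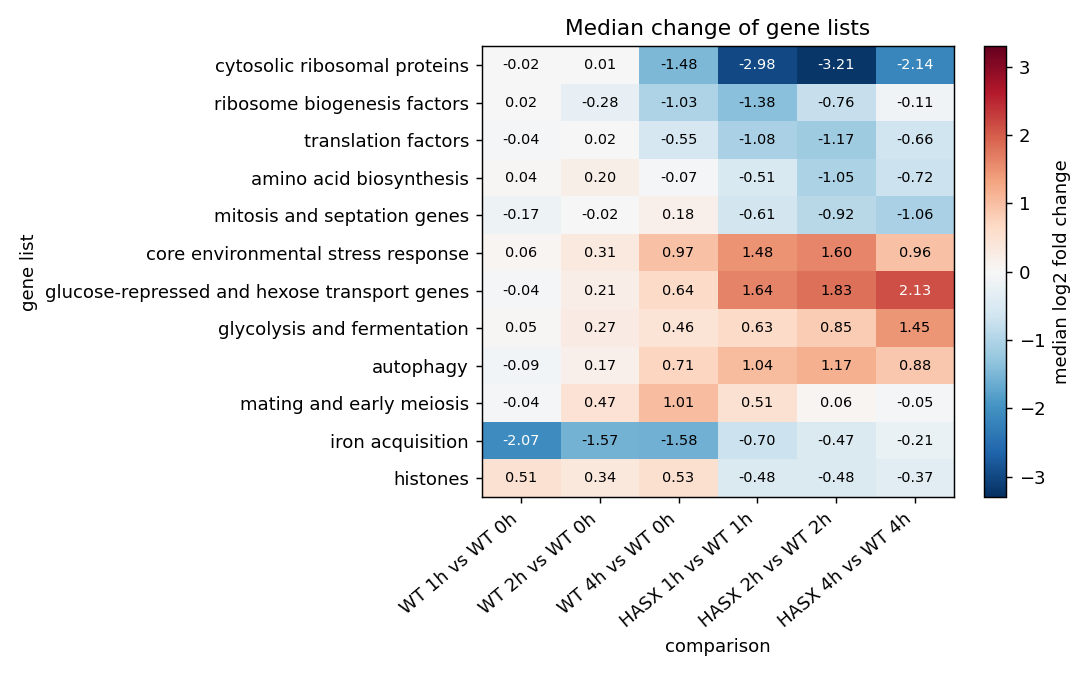
Median log2 fold change (colour and printed value) of 12 gene lists, picked for display after their values were seen, in the 6 comparisons with 0 h or between genotypes. Ribosomal protein genes stood at -1.48 in the wild type at 4 h against 0 h and at -2.98, -3.21 and -2.14 in HASX against the wild type at 1, 2 and 4 h, and medians closer to 0 than 0.09 can change sign with the scaling.

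From 1 h to 4 h in HASX, thiamine and glycolysis genes rose. Levels of nmt1 went from 9.51 ± 0.244 to 560 ± 41.5 CPM (n = 3; log2 5.88, adjusted p = 1.75e-13) and of thi2 from 75.5 ± 5.55 to 1261 ± 10 (4.06, adjusted p = 4.32e-14), while str3 went from 6.16 ± 0.896 to 111 ± 17 (4.16, adjusted p = 0.00239). The dipeptide transporter gene SPCC757.13 fell from 354 ± 69.3 to 36.6 ± 3.55 CPM (-3.28, adjusted p = 1.37e-12) and sam1, of S-adenosylmethionine synthesis, from 2387 ± 771 to 361 ± 8.33 (-2.73). Of the regulon, pho1 (0.74, adjusted p = 0.000234) and pho84 (0.97, adjusted p = 6.95e-06) rose, and tgp1 was at -0.04 (adjusted p = 0.828). In all 628 genes were higher and 304 lower, and without HASX 4 h replicate 3 these were 365 and 451. With only the groups compared in the model 207 were higher and 334 lower, and with the stricter filter 380 and 223. Of 10 thiamine-regulated genes 7 rose and 3 did not pass (7 adjusted over the list alone), at a median of 0.67. Camera put the thiamine list at adjusted p = 3.95e-05, and at adjusted p = 0.425 with an estimated correlation. Of 17 glycolysis and fermentation genes 15 rose and 2 did not pass (15 adjusted over the list alone), at a median of 0.88. With camera the glycolysis list had adjusted p = 4.31e-09, and adjusted p = 0.418 with an estimated correlation. Ribosomal protein genes had 103 of 141 lower, 7 higher and 31 not called (9 up and 105 down adjusted over the list alone), at a median of -0.62. For ribosomal proteins camera gave adjusted p = 6.75e-21, and adjusted p = 0.575 with an estimated correlation.

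The interaction asks whether the change from 1 h to 4 h differed between HASX and the wild type. The log2 rise of pho1 was smaller in HASX, by a difference of -1.16 (adjusted p = 7.26e-05). In CPM its gain was larger in HASX, from 28112 to 46824 against 4944 to 18460 in the wild type. For tgp1, at 1.97 in the wild type and -0.04 in HASX (adjusted p = 0.828), the difference was -2.01 (adjusted p = 1.62e-07). Both genes started from higher levels in HASX at 1 h. For pho84 the difference was -0.21 (adjusted p = 0.358). Genes of the lists for ribosome production were higher in this contrast, which for genes that fell in the wild type means a smaller fall or a rise in HASX: 84 of 92 ribosome biogenesis factors, 1 lower and 7 not called (84 up and 1 down adjusted over the list alone), at a median of 1.29 (camera adjusted p = 5.74e-23; adjusted p = 0.0684 with an estimated correlation), and 109 of 141 ribosomal protein genes, 1 lower and 31 not called (114 up and 1 down adjusted over the list alone), at a median of 0.80. Camera put ribosomal proteins at adjusted p = 1.37e-23, and at adjusted p = 0.573 with an estimated correlation. Lower were 14 of 27 mating genes, with 1 higher and 12 not called (1 up and 17 down adjusted over the list alone), at a median of -0.95 (camera adjusted p = 2.95e-05; adjusted p = 0.12 with an estimated correlation), and urg1 at -4.95 and urg2 at -4.78. In all 799 genes were higher and 623 lower, and 643 and 745 without HASX 4 h replicate 3. Among named genes spo6 had the highest value, 7.46, which was 1.95 without that library (adjusted p = 0.0507).

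Against the wild type in replete medium at 0 h, HASX had 1444 genes higher and 1384 lower at 1 h, 1498 and 1508 at 2 h, and 1768 and 1483 at 4 h. These comparisons hold genotype and starvation together, as there was no HASX group at 0 h.

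The wild-type change at 4 h and the genotype difference at 1 h, which share no library, were compared across genes. Of the 509 genes higher in the wild type at 4 h, 391 were also higher in HASX at 1 h and 15 were lower, where independence gives 120 in common. Of the 566 lower genes 356 were lower in HASX and 26 higher, where independence gives 125 lower. Across 6234 genes Pearson's r was 0.54 and Spearman's rho 0.49. The wild-type change at 1 h had r of -0.073 and rho of -0.134 with the genotype difference at 4 h, and r of -0.062 and rho of -0.128 with that at 2 h. Of the 48 genes higher in the wild type at 1 h, 26 were higher and 5 lower in HASX at 4 h, and 32 higher and 5 lower at 2 h, where independence gives 11.9 and 12.3 higher. Of the 89 lower genes 11 were lower and 34 higher in HASX at 4 h, and 10 lower and 41 higher at 2 h, where independence gives 16.6 and 21.2 lower. These are 3 relations across genes, and genes are not independent replicates, so no p is given.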

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

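The tests of explanations in this part were chosen after the values were seen, except the count of neighbouring genes among those raised in HASX 4 h replicate 3. The interaction, its list medians, the DESeq2 size factors and the thinned counts were planned, and only their use against an explanation was chosen later. Single libraries were not tested as outliers of their groups of 3.

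The interaction of genotype and time drew attention because the change from 1 h to 4 h differed between HASX and the wild type for 799 genes upward and 623 downward. The difference was -1.16 for pho1 and -2.01 for tgp1. Upward differences among named genes were 7.46 for spo6, 5.52 for SPAC22E12.02, 5.35 for str3, 4.37 for nmt1, 4.10 for thi2, 3.92 for psu2, 3.77 for SPAC23C4.09c and 3.50 for mpf2. Without HASX 4 h replicate 3, spo6 was at 1.95, SPAC22E12.02 at 0.94, SPAC23C4.09c at 2.1 and mpf2 at 1.97. Downward differences were -5.84 for the esterase gene SPAPB1A11.02, -4.95 for urg1, -4.78 for urg2, -4.53 for SPAC11D3.03c, -4.53 for SPAC1399.01c, -4.45 for SPAPB1A11.03, -4.16 for the nucleoside hydrolase gene SPBC800.11 and -4.02 for SPCC757.13. List medians with a difference were 0.80 for ribosomal proteins, 1.29 for ribosome biogenesis, 1.08 for RNA polymerase I and III, 0.81 for translation factors, 0.75 for chaperones and 0.64 for thiamine genes, and -0.72 for nitrogen starvation, -0.95 for mating, -0.55 for autophagy and -0.60 for mitosis and septation. With camera these 10 lists had adjusted p from 1.37e-23 to 0.00215, and from 0.0684 to 0.629 with an estimated correlation, where 0 passed. In a model of these groups alone 1279 genes were called, and 5 of 100 splits of the libraries, the real one included, gave as many, with 2394 as the highest other. The 4 splits with more calls exchanged 2 of 3 libraries at 4 h and none at 1 h, which turns the difference between the genotypes into an interaction by construction. These splits therefore do not show whether chance can be excluded.

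HASX 4 h replicate 3 stood apart from all other libraries. Of 5749 genes with at least 50 counts in that library, 470 were at least 4-fold above both its partners. Of these 332 were long non-coding and 136 protein-coding. The deleted gene siw14 stood in it at 27.2% of the wild-type level above its partners, but the median over mfm2, mam2, aps1 and pqr1 was 1.44%, which argues against an admixture of wild-type RNA. With 18.27 M counts it was the deepest library of its group, which argues against low depth. Of the raised genes 14 pairs were neighbours, against 33.6 in random draws. The draws took no account of gene class or level, while 332 of the 470 raised genes were long non-coding. This count therefore does not decide on reads from long stretches of the genome. No biological explanation was tested, and what set this library apart stays open.

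Ribosomal protein genes were lower in HASX than in the wild type from 1 h on. In counts thinned to 1 depth for all libraries the median at 1 h was -2.98, as with all counts. This argues against a difference in depth only weakly, since values are scaled to library size and random thinning keeps each gene's expected share. With DESeq2 size factors the median of the list was -2.93, but these moved the median of all genes by only 0.046. They take most genes as unchanged, as TMM does, so a change in total RNA stays open. The fold changes of the wild type at 4 h and those of HASX at 1 h correlated across genes at r = 0.54. Such an r could come from HASX being, after 1 h, in a state that the wild type approaches later. This hypothesis was found and tested on the same data. Not all lists moved alike: ribosomal proteins fell in both (medians of -1.48 and -2.98), but histones stood at 0.53 and -0.48. Without HASX at 0 h, a difference present before starvation cannot be told apart from such a state. Effects of strain differences other than the 4 mutations, among them ura4, which had counts in HASX only, were not tested and stay open. So does a preparation that differed between the genotypes.

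The uracil-regulated genes urg1, urg2 and urg3 and the pyrimidine salvage genes uck2, urh1 and cdd1 fell in the wild type at 1 h. In this order they were higher in HASX than in the wild type at 1 h, with log2 values of 6.27, 5.54, 3.42, 5.03, 2.98 and 4.07. Against the wild type at 0 h the values of HASX at 1 h were 2.15, 1.58, 0.58, 1.22, 0.05 (adjusted p = 0.765 for urh1) and 1.67, so part of each difference is the fall in the wild type. These 6 genes were put together after their values were seen. An effect of the ura4 marker on the level in HASX was not tested and stays open. Whether the transfer to other medium or the lack of phosphate caused the fall cannot be told apart without a mock transfer, and the median change of the 6 genes from 1 h to 4 h was 2.80, a return that either could give.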

How the results depend on the processing

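Leaving HASX 4 h replicate 3 out of comparisons that do not use it was chosen after the data were seen, and all other alternatives before. For named genes, with DESeq2 size factors 1094 values kept direction and side of the threshold, 24 lost and 2 gained a call, and 0 reversed. With DESeq2 1088 kept it and 5 lost it, with no filter 1111 and 9, with the stricter filter 1098 and 1, in thinned counts 1094 and 24, with the replicate number as a block 1083 and 36, and with only the groups compared 1015 and 96. When a replicate was left out 7678 values kept their call, 527 lost it and 7 reversed. At these depths the filter on low counts left 6234 of 6988 genes.

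Counts of genes stayed within 1.5 times of the reported ones, except 51 higher at 2 h in the wild type with only the groups compared, and 380 with the stricter filter and 207 with only the groups compared for genes higher at 4 h than at 1 h in HASX. Leaving out 1 replicate gave 40 to 221 lower genes at 2 h in the wild type (118 without HASX 4 h replicate 3) and 365 to 768 higher genes from 1 h to 4 h in HASX. The stricter filter tests fewer genes (5240) and the models of the groups compared hold fewer libraries; otherwise the cause was not tested. DESeq2 called the deleted genes lower in 6 of 9 tests, and gave siw14 no adjusted p in the other 3. The correlation of the wild type at 4 h with HASX at 1 h was 0.59 with the stricter filter.

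With the correlation estimated per list and comparison, at -0.08 to 0.9 against the preset 0.01, 0 of 109 list calls were kept. With fry 5 lists took the other direction, and the cause was not tested: phospholipid genes in HASX at 1 h (adjusted p = 0.0271), purine and pyrimidine synthesis at 1 h (0.39) and 4 h (0.00154), and RNA polymerase I and III (0.0459) and copper and zinc transport (0.0418) at 4 h. Without HASX 4 h replicate 3 some values reversed, since that library alone held the rise. Over the libraries left out, asp1 ranged from -0.02 to 1.17 against the wild type at 4 h, from -0.07 to 1.12 against 1 h and from -0.73 to 0.46 in the interaction. For siw14 the ranges were -0.49 to 3.50 against 1 h and -1.27 to 2.72 in the interaction, and for pcf11 -0.53 to 1.90 against the wild type and 0.00 to 2.43 against 1 h, each lowest without that library.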

Other observations

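The tests in this part were chosen after the values were seen, except the one on neighbours of long non-coding RNAs. Some genes of the M mating type were low in HASX, although the labels give both strains the same mating type. The genes were chosen after their values were seen, apart from mfm2, mfm1 and mam2. The mating gene ste6, which is not particular to M cells, was at -1.75, -2.74 and -2.18 against the wild type at 1, 2 and 4 h. Of the M genes, mam2 was at -1.90, -3.21 and -4.09, and mfm1 at -0.39 (adjusted p = 0.12), -1.28 and -3.00. Others were not low at 1 h: mam3 was at 1.08, -0.06 and -0.60, mam1 at 0.00, -1.18 and -1.24, and mfm3 at 0.13, 0.15 and -2.24. The P-cell receptor gene map3 was at 1.37, 0.22 and -0.33. A switch of HASX cells to the P type could lower M genes, but a switch of any share of the cells would lower them alike. That holds only for genes that M cells alone express and whose levels leave room for such a fall. The 7 genes lay 6.55, 6.63 and 6.56 apart at 1, 2 and 4 h, from mfm2 to the highest of the others. The standard errors of these gaps were 0.33, 0.48 and 0.35, and ste6 was at neither end of them. The highest at 2 h was mfm3, which at 1.5 CPM in the wild type could not show a fall as large as that of mfm2. At 1 and 4 h the highest was mam3, which stood at 53, 75 and 118 CPM in the wild type at 1, 2 and 4 h. If M cells alone express mam3, its values argue against a switch as the only cause. The P-cell list had medians of 1.17, 0.22 and 0.10, and its highest member at 4 h, map2 at 3.0, was at 1.67 without HASX 4 h replicate 3. What lowered the M genes stays open.

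Single genes of other lists differed between the genotypes, in both directions. In HASX at 1 h the copper and zinc list had 6 of 12 genes higher and 6 lower (6 and 6 adjusted over the list alone), at a median of 0.09. The metallothionein gene zym1 stood at 1793 ± 55.2 CPM (n = 3) in HASX at 1 h and 28.9 ± 3.05 in the wild type, and at 11257 ± 1142 and 251 ± 2.27 at 4 h. The polyphosphate synthase subunit gene vtc4 stood at 494 ± 41.1 CPM in HASX and 275 ± 8.51 in the wild type at 1 h, and vtc2 at 445 ± 75.4 and 993 ± 31.4 at 4 h. The phospholipid methyltransferase gene cho2 stood at 52.3 ± 3.94 CPM in HASX and 795 ± 96.2 in the wild type at 2 h, and the phospholipase gene plb5 at 199 ± 7.99 and 13.7 ± 1.36.

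Long non-coding RNAs were higher in HASX more often than protein-coding genes, and their share of all counts was 1.90% ± 0.180, 2.20% ± 0.0448 and 2.80% ± 1.74 (n = 3) at 1, 2 and 4 h, with a range of 1.59% to 4.80% at 4 h. In the wild type the group means lay between 0.985% and 1.08%. Reading on from a raised neighbouring gene could give this, which was tested at 1 h only. There 35.7% of raised long non-coding RNAs (187 of 524) had a raised protein-coding neighbour against 32.1% of the others (190 of 592). The ratio of 1.11 (permutation p = 0.113 over 10000 draws) argues against reading on from an adjacent raised protein-coding gene as the main source at 1 h. The test took neighbours on either side without regard to strand. Reading on from a neighbour that was not itself raised was not tested and stays open. The shares of snoRNA, snRNA and rRNA were higher in HASX too, at 0.0567%, 0.00208% and 0.0274% at 1 h against 0.0147%, 0.000149% and 0.00419% in the wild type. At 4 h the rRNA share in HASX ranged from 0.0115% to 0.446%. Over 3 classes and 3 times the ratio of the means was at least 3.85, and at least 1.78 when any 1 library was left out. The lowest was for rRNA at 4 h without HASX 4 h replicate 2, against 22.8 with all libraries. Without HASX 1 h replicate 2 the ratios at 1 h were 6.18 for snRNA and 2.99 for rRNA, and without HASX 4 h replicate 2 that of snRNA at 4 h was 7.15, against 19.1 with all libraries. Libraries of the genotypes did not overlap, where chance gives no overlap in 10% of comparisons of 3 with 3. This is consistent with RNA quality or polyA selection that differed between the genotypes' libraries, and a change in the RNAs themselves stays open as well. The strand setting of the counting is unknown, so antisense signal stays open.

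For the comparisons of 3 libraries with 3, the 10 splits cannot give a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0. The real counts, in models of the groups compared alone, were 161, 99 and 1134 for the wild type at 1, 2 and 4 h against 0 h, 2871, 3087 and 2419 for HASX against the wild type at 1, 2 and 4 h, 942 and 541 for 4 h against 1 h in the wild type and HASX, and 2845, 3062 and 2996 for HASX against the wild type at 0 h.

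In HASX 4 h replicate 3, SPAC343.20 had 80025 counts against 15 and 25 in its partners, and the non-coding RNA SPNCRNA.832 had 59354 against 10 and 14. Both were chosen after their values were seen. No subset of the 3 HASX 4 h libraries gave the authors' deposited fold changes for that group, with median differences of 0.173 to 0.294.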
